A study of Mus musculus with 19 samples.

How the data were processed

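Polyadenylated RNA was measured in single mouse blastocysts, the stage at which the inner cell mass and the trophectoderm have parted, with 1 library per embryo. The libraries fall into 9 Padi6-mutant and 10 Control embryos by the genotype in the labels, and each embryo counts as 1 biological replicate. Per the labels, RNA and DNA of each embryo were separated with the G&T protocol, cDNA was made by template switching on oligo-dT beads and amplified by PCR, and libraries were made with Nextera XT and read in pairs. The labels name no litter, day or batch. All tests took embryos as independent, so their p-values may be too small if embryos of a group share a litter. They speak of 20 pooled libraries, of which 19 were used here, and they do not say whether the sequenced embryos went through the culture that they describe for outgrowth measurements.

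Per the labels, reads were trimmed with Trim Galore 0.4.4 and aligned with HISAT2 2.1.0, and the builds GRCm39 and mm39 are named, while the counting tool and the gene annotation are not stated. The deposited table holds log2 values of 14173 listed genes. Taken back from the log2 scale, every value lay within 1.96e-07 of a whole number, read as a scaled count plus 1. The authors scaled each library by 1 factor so that the upper quartile over the listed genes is the same in all 19 libraries. Every listed gene was above 0 in at least 9 libraries, so a filter on genes above 0 in 9 libraries, the size of the smaller group, removed none. No pair of libraries was a duplicate: the highest Spearman's rho between 2 libraries was 0.972, and at most 1.18% of genes had an identical scaled count in 2 libraries.

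Groups were compared with limma 3.58.1 (lmFit and eBayes with a trend, two-sided) in R 4.3.3 on the deposited log2 values, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists with 2 or more measured members, beside camera with an estimated correlation and fry, which tests whether the members of a list move on balance in 1 direction. The 22 lists covered the lineages of the blastocyst (inner cell mass, primitive endoderm, trophectoderm), imprinted genes expressed from the paternal or the maternal allele, the machineries of DNA methylation and of H3K9 methylation, germline genes silenced by DNA methylation, the X inactivation centre, the subcortical maternal complex, oocyte transcripts, genes of the 2-cell stage, targets of p53, the integrated stress response, the interferon response, cholesterol synthesis, glycolysis, transcripts of the mitochondrial genome, cytosolic ribosomal proteins, the cell cycle, cumulus and granulosa cells, and Y-linked genes. The mean of each list per embryo was compared with an exact two-sided permutation test over all 92378 splits, adjusted over the 22 lists, as a further check chosen after the values were seen. A score per embryo (mean of the inner cell mass list minus mean of the trophectoderm list) and a distance per embryo (root mean square log2 difference from the mean of the other embryos of its group) were compared with the same exact test.

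The lists, tests, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made later. Named genes were Padi6, 8 regulators of DNA methylation or imprints (Dnmt1, Uhrf1, Dnmt3a, Dnmt3b, Dnmt3l, Dppa3, Zfp57, Trim28) and 5 lineage factors (Nanog, Pou5f1, Sox2, Gata6, Cdx2), whatever their p; the 10 largest rises and the 10 largest falls among genes past the threshold with a mean above the median of all genes, leaving out unnamed gene models; and from each list up to 4 members with the smallest adjusted p, or, where none passed, up to 2 with the highest mean. Genes named beyond this rule are said to be so, and some genes that meet it are not reported here.

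Transcript length and GC content were looked up by symbol in GENCODE release M 21, whose build is older than the one in the labels, so no coordinates were taken from it other than the chromosome. The shortest principal (APPRIS) transcript of each gene was used, or the longest coding transcript where none is principal; 13357 genes (94.2%) had a length and 10982 (77.5%) a principal transcript. A trend on length and on GC content was fitted to each library's deviation from the gene means by lowess with a span of 0.3 and removed, as an alternative chosen after seeing the data. The same trend was also removed with the longest transcript of each gene, and with the trend fitted on genes with a principal transcript alone. In the same way libraries were thinned at random to the depth of the shallowest one, which covers counting error alone and took 1 scaled count as 1 count in the 6 libraries whose step could not be told, and the 4 mutant libraries with over 400 genes at 0 were left out. The alternatives fixed before the values were read were a block for the number in the library name, quantile normalization, a stricter filter, library quality weights, the Y-linked level or the number of detected genes as a covariate, limma without the trend, an added fold threshold, a pseudocount of 0.1, a median in place of a mean, and leaving out each library in turn.

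The steps were tested on simulated data of the same group sizes. At an added log2 change of 0.5, 5.97% of changed genes were recovered, against 34.3% at 1 and 69.7% at 2, and 1 of 74 calls was false. The 1 shifted list was called and 0 others. The simulated genes were independent of each other, whereas members of the ribosomal protein list had an estimated correlation of 0.80. The simulation therefore cannot show how often lists of correlated genes are called falsely. Figures were drawn with Python 3.11.15.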

Results

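Transcript levels of single mouse blastocysts were compared between 9 Padi6-mutant and 10 Control embryos, to ask which genes differ with the Padi6 genotype. Padi6 encodes a protein of the oocyte cytoplasm that belongs to the subcortical maternal complex, which is laid down before fertilization and lasts into early cleavage. Values are log2(scaled count + 1) for 14173 genes. The original counts in the listed genes could be worked out from the smallest step between values in 13 libraries, and lay between 27.9 and 46.2 M in 5 Control libraries (mean 33.7 ± 7.43, SD) and between 12.1 and 30.2 M in 8 Padi6-mutant libraries (mean 20.6 ± 6.27, SD). These counts are above the mean depth of 4.2 M reads in the labels, a difference that was not resolved, and the thinned values rest on them. In Control 1, 2, 3, 4 and 7 and in Padi6-mutant 7 the step could not be told. Padi6-mutant libraries had 312 ± 191 genes at 0 (SD, n = 9) against 117 ± 76.2 in Control libraries (SD, n = 10; exact permutation p = 0.00890). The 18S ribosomal RNA took 4.89 ± 1.26% of the scaled counts in Padi6-mutant and 9.55 ± 4.69% in Control libraries (exact permutation p = 0.00556), and mitochondrial transcripts took 7.09 ± 2.05% and 5.55 ± 1.88% (exact permutation p = 0.103).

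Padi6 itself was measured at 6.49 ± 2.16 in Padi6-mutant embryos (SD, n = 9) and 6.53 ± 1.503 in Control embryos (SD, n = 10), a log2 fold change of -0.04 (SE 0.78, adjusted p = 0.976) on chromosome 4. The largest coordinated differences lay elsewhere. Of 77 cytosolic ribosomal protein genes, 70 rose in Padi6-mutant embryos, with a list median of 2.22. Of 95 nuclear genes of the respiratory chain and ATP synthase, 81 rose while 0 fell. This group was chosen after its values were seen and includes assembly factors of complex I (Ndufaf genes). Short transcripts outside these groups rose as well, with 746 of 1719 under 1000 nt higher and 33 lower. Of 23 cholesterol synthesis genes, 20 fell, with a median of -1.37. Markers of the primitive endoderm (7 of 18 lower) and of the inner cell mass (7 of 22 lower, 1 higher) were lower as groups, while 7 of 25 trophectoderm markers rose and 2 fell. With a correlation between genes estimated from the data in place of the preset one, 0 of these lists was called (adjusted p = 0.594 for each of the 6 lists called at the preset correlation).

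Across all 14173 genes, 3765 (26.6%) changed at a limma adjusted p under 0.05, 2068 higher and 1697 lower in Padi6-mutant embryos, and 5460 passed an unadjusted p of 0.05. The median log2 fold change of all genes was -0.10. The first principal component held 23.2% of the variance, and Padi6-mutant libraries scored 38.5 to 109.8 on it against -111 to 15.0 for Control libraries (exact permutation p = 2.17e-05, the smallest that the 92378 splits can give). Without the 4 Padi6-mutant libraries with over 400 genes at 0, namely 6, 8, 9 and 10, 2622 genes changed, of which 941 were lower. With the number of detected genes as a covariate, 1807 genes changed, of which 499 were lower and 1710 were among the 3765. In either case 2 of the 6 called lists, ribosomal proteins and cholesterol synthesis, stayed called.

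The sign of the Padi6 value turned without Control 5, 6, 7 or 9 or without Padi6-mutant 2, 7, 9 or 10 (range -0.39 to 0.52 over the left-out libraries), so no direction can be read from it. Of 22 measured genes of the DNA methylation machinery, 5 fell and 1 rose, and the same numbers passed when adjusted over the list alone. Dnmt1, the maintenance methyltransferase, fell by 0.70 (SE 0.20, adjusted p = 0.0101), and Uhrf1, which brings it to hemimethylated DNA, fell by 0.81 (SE 0.27, adjusted p = 0.0291). Tet1, a dioxygenase that oxidizes 5-methylcytosine, fell by 1.16 (adjusted p = 0.00235), or by 0.67 without the 4 libraries with over 400 genes at 0. Trim28, the corepressor that zinc-finger proteins recruit to imprinted regions, fell by 0.99 (adjusted p = 0.00320), and Mbd1, a reader of methylated DNA, fell by 0.66 (adjusted p = 0.0147). Dppa3, which guards maternal methylation in the zygote, rose by 1.12 (adjusted p = 0.0243). The values of Dnmt3a (0.04), Dnmt3b (-0.36), Dnmt3l (0.47) and Zfp57 (-0.66) did not pass, with adjusted p of 0.912, 0.189, 0.0883 and 0.289. Zfp57 lay at -0.21 without Padi6-mutant 10. The list was not called (adjusted p = 0.186), and its median relative to all genes, -0.20, became 0.03 after removal of the trend on transcript length and GC content. After that removal Tet1 still passed (-0.97, adjusted p = 0.0122), whereas Dnmt1 (-0.27, adjusted p = 0.203), Uhrf1 (-0.47, adjusted p = 0.150), Trim28 (-0.47, adjusted p = 0.0806), Mbd1 (-0.36, adjusted p = 0.157) and Dppa3 (-0.12, adjusted p = 0.720) did not, and Dnmt3l did (0.56, adjusted p = 0.0125). The call of Uhrf1 ended without Control 1, 2, 7 or 10 or Padi6-mutant 4 or 6 (highest adjusted p = 0.0563), and that of Dppa3 without Control 1 (adjusted p = 0.0504). The calls of Dnmt1 (-0.34, adjusted p = 0.313), Uhrf1 (-0.33, adjusted p = 0.496), Tet1 (-0.64, adjusted p = 0.132), Trim28 (-0.49, adjusted p = 0.175), Mbd1 (-0.71, adjusted p = 0.0580) and Dppa3 (1.00, adjusted p = 0.155) ended with the number of detected genes as a covariate. The calls of Dnmt1 (-0.54, adjusted p = 0.111), Uhrf1 (-0.66, adjusted p = 0.125) and Trim28 (-0.68, adjusted p = 0.0851) ended without the 4 libraries with over 400 genes at 0. The call of Dppa3 (0.74, adjusted p = 0.0759) ended under quantile normalization.

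Inner cell mass and pluripotency markers were lower as a list (median -0.76, camera adjusted p = 0.0242; adjusted p = 0.594 with an estimated correlation), with 7 of 22 lower and 1 higher, and the same numbers adjusted over the list alone. Pou5f1, the core pluripotency factor, fell by 1.26 (SE 0.27, adjusted p = 0.00158), below the Control median in 9 of 9 Padi6-mutant embryos. The naive pluripotency factors Tfcp2l1 (-0.79) and Tbx3 (-0.74) and the adhesion molecule Pecam1 (-2.04) fell as well. Dppa5a, an RNA-binding protein of pluripotent cells, rose 4.27-fold (adjusted p = 1.67e-05). Tfcp2l1 stood at -1.22 under quantile normalization and at -0.52 with the trend fitted on genes with a principal transcript alone. Pecam1 stood at -0.93 without the 4 libraries with over 400 genes at 0. Tbx3 (-0.35) and Dppa5a (0.62) moved on removal of the length and GC trend. Nanog (0.01, adjusted p = 0.982) and Sox2 (-0.93, adjusted p = 0.459) did not pass. Sox2 was at 0 in Padi6-mutant 10 and turned to 0.10 without that library, so no direction is read from it. The list lost its call without Padi6-mutant 10, where it lay 0.28 below all genes (adjusted p = 0.0996), and without the 4 libraries with over 400 genes at 0 it lay 0.08 below (adjusted p = 0.329). It was not called either over genes above the median level (adjusted p = 0.0795), with library quality weights (adjusted p = 0.0605) or with the number of detected genes as a covariate (adjusted p = 0.348). The calls of Pou5f1 (-0.87, adjusted p = 0.0710) and Pecam1 (-0.55, adjusted p = 0.598) ended with the number of detected genes as a covariate. The call of Tbx3 (-0.31, adjusted p = 0.0958) ended with the trend of the longest transcript removed. The calls of Tbx3 (-0.31, adjusted p = 0.0814) and Dppa5a (0.20, adjusted p = 0.319) ended with the trend fitted on genes with a principal transcript alone. The mean of the list per embryo was 11.2 ± 0.89 in Padi6-mutant (SD, n = 9) and 11.8 ± 0.23 in Control (SD, n = 10), with an exact permutation p of 0.0136, or 0.0499 adjusted over the 22 lists.

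Primitive endoderm markers were lower as a list (median -1.08, camera adjusted p = 0.00482; adjusted p = 0.594 with an estimated correlation), with 7 of 18 lower and 0 higher, or 12 lower adjusted over the list alone. The laminin chains Lamc1 (adjusted p = 9.74e-04) and Lamb1 (-1.46), the endocytic receptor Cubn (-1.97) and the collagen chain Col4a1 (-1.35) fell, as did Gata6, the factor that specifies this lineage (-0.59, adjusted p = 0.0233), and the growth factor receptor Pdgfra (-2.51, adjusted p = 0.0282). Pdgfra lost its call without Padi6-mutant 9 (adjusted p = 0.0512). It stood at -1.61 without Padi6-mutant 10 and at -0.97 without the 4 libraries with over 400 genes at 0. Lamc1 stood at -0.55 after removal of the length and GC trend. After removal of the length and GC trend the list lay 0.71 below all genes and was not called (adjusted p = 0.141), with Gata6 at -0.14 (adjusted p = 0.580), Col4a1 at -0.76 (adjusted p = 0.192) and Pdgfra at -2.28 (adjusted p = 0.0572). Without the 4 libraries with over 400 genes at 0 it lay 0.59 below (adjusted p = 0.122), and with the number of detected genes as a covariate 0.35 below (adjusted p = 0.308). The calls of Lamb1 (-1.04, adjusted p = 0.0749), Cubn (-1.58, adjusted p = 0.116), Col4a1 (-0.42, adjusted p = 0.539), Gata6 (-0.51, adjusted p = 0.159) and Pdgfra (-0.72, adjusted p = 0.620) ended with the number of detected genes as a covariate. The calls of Col4a1 (-0.69, adjusted p = 0.223) and Gata6 (-0.62, adjusted p = 0.0827) ended without the 4 libraries with over 400 genes at 0.

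Trophectoderm markers were not called as a list (median 0.08, adjusted p = 0.677), and their median relative to all genes turned from 0.18 to -0.10 under quantile normalization. It also turned without Padi6-mutant 7 (-0.0014), 9 (-0.04) or 10 (-0.07). Of 25 measured, 7 rose and 2 fell, and the same numbers passed adjusted over the list alone. Dppa1 (2.01), the tetraspanin Tspan8 (1.48), the transcriptional inhibitor Id2 (1.15) and the placental gene Plac1 (1.85) rose. The 2 that fell, Wnt7b (-0.91) and Krt7 (-0.77), were chosen after their values were seen. Cdx2, the factor of the trophectoderm, did not pass (-0.36, adjusted p = 0.214). After removal of the length and GC trend Dppa1 (0.32, adjusted p = 0.548; -0.21 with the trend fitted on genes with a principal transcript alone), Tspan8 (0.69, adjusted p = 0.124), Id2 (0.53, adjusted p = 0.276) and Plac1 (0.93, adjusted p = 0.293) no longer passed. Cdx2 passed under quantile normalization (-0.63, adjusted p = 0.0468). The calls of Id2 (1.21, adjusted p = 0.0593) and Plac1 (1.89, adjusted p = 0.0815) ended with the number of detected genes as a covariate.

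**Figure D1:**
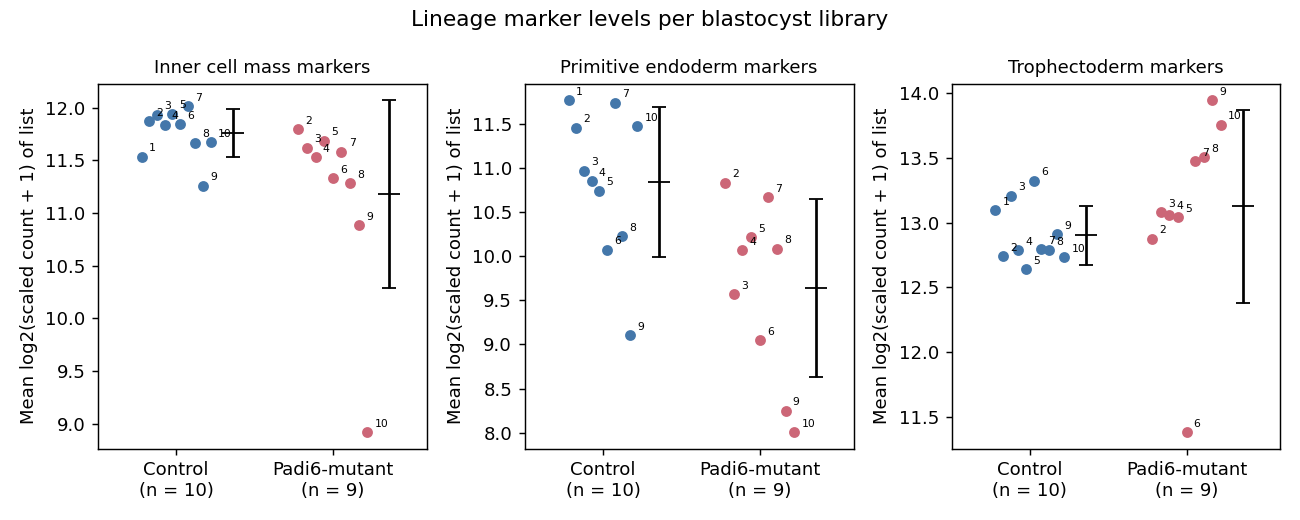
Mean log2(scaled count + 1) of the inner cell mass, primitive endoderm and trophectoderm lists in each blastocyst library, with points numbered by library and bars for the group mean and SD (n = 10 Control, n = 9 Padi6-mutant). Padi6-mutant 10 has the lowest inner cell mass value (8.92) and Padi6-mutant 6 the lowest trophectoderm value (11.4).

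Per embryo, the inner cell mass score minus the trophectoderm score was -1.94 ± 1.36 in Padi6-mutant (SD, n = 9) and -1.14 ± 0.33 in Control embryos (SD, n = 10), a difference of -0.80 that did not pass (exact permutation p = 0.0814). Padi6-mutant 10 had the lowest value (-4.83) and Padi6-mutant 6 the highest (-0.05). Without Padi6-mutant 6 the difference was -1.04 (exact permutation p = 0.00654), without Padi6-mutant 10 it was -0.44 (exact permutation p = 0.172), and without the 4 libraries with over 400 genes at 0 it was -0.32 (exact permutation p = 0.0946). The distance of an embryo from the mean of its group was 1.23 ± 0.27 in Padi6-mutant (SD, n = 9) and 1.08 ± 0.20 in Control embryos (SD, n = 10), which did not pass either (difference 0.15, exact permutation p = 0.174). Over genes above the median level this difference turned to -0.05, and without the 4 libraries with over 400 genes at 0 to -0.06.

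Cytosolic ribosomal protein genes rose as a list (median 2.22, camera adjusted p = 5.43e-43; adjusted p = 0.594 with an estimated correlation), with 70 of 77 higher and 0 lower, and the same numbers adjusted over the list alone. The small-subunit proteins Rps27 (3.24, SE 0.32) and Rps28 (2.90, SE 0.28), the Rps27 relative Rps27l (2.86) and the large-subunit protein Rpl34 (2.91) had the smallest adjusted p, and each was above the Control median in 9 of 9 Padi6-mutant embryos. The list mean per embryo was 15.0 ± 0.51 in Padi6-mutant (SD, n = 9) and 13.1 ± 0.73 in Control (SD, n = 10), with an exact permutation p of 6.50e-05, or 0.00143 adjusted over the 22 lists. The other 9 of the 10 largest rises among genes with a mean above the median were mostly genes of mitochondrial proteins. They were mt-Nd3 (3.61), Ndufa5 (3.47), Ndufa1 (3.40) and Ndufb1 (3.27), subunits of respiratory complex I, Ndufa4 (3.19), a subunit tied to cytochrome c oxidase, Atp5mk (3.39) and Atp5me (3.37) of the ATP synthase, Dnajc19 (3.13), a cochaperone of mitochondrial import, and the prolyl isomerase Pin4 (3.20). Of the 13 protein-coding transcripts of the mitochondrial genome, 6 rose and 0 fell, or 8 and 0 adjusted over the list alone (median 0.84, camera adjusted p = 0.00346; adjusted p = 0.594 with an estimated correlation), among them the complex I subunits mt-Nd1 (1.27), mt-Nd2 (1.25) and mt-Nd6 (0.86). That list was not called without the 4 libraries with over 400 genes at 0 (adjusted p = 0.197) or with the number of detected genes as a covariate (adjusted p = 0.337). The calls of mt-Nd1 (0.74, adjusted p = 0.281), mt-Nd2 (0.71, adjusted p = 0.265) and mt-Nd6 (0.62, adjusted p = 0.185) ended with the number of detected genes as a covariate. The calls of mt-Nd1 (0.97, adjusted p = 0.139), mt-Nd2 (0.99, adjusted p = 0.119) and mt-Nd6 (0.79, adjusted p = 0.0877) ended without the 4 libraries with over 400 genes at 0. The call of mt-Nd1 (0.65, adjusted p = 0.111) ended under quantile normalization.

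These rises went with transcript length. Genes in the shortest of 10 length classes, up to 768 nt, had a median log2 fold change of 1.28 with 684 higher and 25 lower, against -0.31 with 33 higher and 265 lower in the longest class. Within each library, the Spearman's rho of transcript length with the deviation from the gene means, taken across genes, which are not independent replicates, was -0.25 ± 0.12 in Padi6-mutant (SD, n = 9) and 0.17 ± 0.18 in Control (SD, n = 10; exact permutation p = 1.30e-04). Control 5 (-0.12) and Control 9 (-0.11) lay below the highest Padi6-mutant library (-0.09). After removal of the length and GC trend of each library, 57 of the 77 ribosomal protein genes were still higher and 2 lower (median 0.98, camera adjusted p = 2.42e-35; adjusted p = 0.406 with an estimated correlation). With the trend fitted on genes with a principal transcript alone, 44 were higher and 2 lower, and Rps28 turned to -0.18 (adjusted p = 0.343). Single genes shrank alike, from the first to the latter removal, with Rps27 at 1.53 and 0.42, Rpl34 at 1.29 and 0.65, and Rps27l at 1.06 and 0.43. The mitochondrial genes Ndufa1 (1.57 and 0.77), Ndufa4 (1.32 and 0.59) and Dnajc19 (1.62 and 1.23) did too, as did Pin4 (1.47 and 0.83). No length was found for Atp5mk, Atp5me and Ndufb1, so the removal was not run for them. The mitochondrially encoded list lay 0.94 above all genes before and 0.18 below them after removal (adjusted p = 0.492), with mt-Nd6 then lower (-0.93, adjusted p = 0.00183). With the trend fitted on genes with a principal transcript alone that list was called lower at the preset correlation (0.27 below all genes, adjusted p = 0.00157). At an estimated correlation it was not called in the values as deposited (adjusted p = 0.594) or after the first removal (adjusted p = 0.885). With the principal-transcript trend mt-Nd3, at 1.71 after the first removal, did not pass (0.38, adjusted p = 0.284). The direction of the list thus rests on how length and GC content are corrected.

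**Figure D2:**
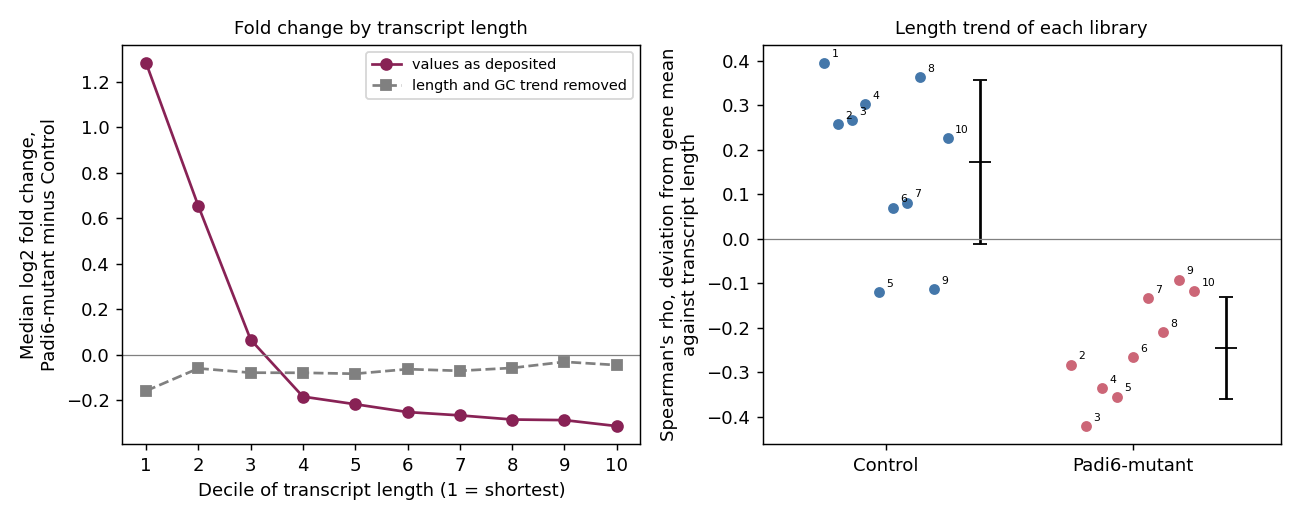
Left, median log2 fold change (Padi6-mutant minus Control) of genes in 10 classes of transcript length, from the values as deposited and after removal of each library's trend on length and GC content; the shortest class falls from 1.28 to -0.16. Right, Spearman's rho across genes between transcript length and a library's deviation from the gene means, 1 numbered point per library with group mean and SD (n = 10 Control, n = 9 Padi6-mutant); all Padi6-mutant libraries are below 0, as are Control 5 and 9.

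Cholesterol synthesis genes fell as a list (median -1.37, camera adjusted p = 4.83e-09; adjusted p = 0.594 with an estimated correlation), with 20 of 23 lower and 0 higher, and the same numbers adjusted over the list alone. Hmgcs1, a synthase early in the pathway, fell by 1.41 (SE 0.22). The squalene epoxidase Sqle (-2.55) and the lanosterol demethylase Cyp51 (-2.28) were among the 10 largest falls of genes with a mean above the median, with the fatty acid synthase Fasn (-2.99) and the stearoyl-CoA desaturase Scd2 (-2.26). Each of these genes was below the Control median in 9 of 9 Padi6-mutant embryos. The list mean per embryo was 10.70 ± 0.55 in Padi6-mutant (SD, n = 9) and 11.99 ± 0.77 in Control (SD, n = 10), with an exact permutation p of 0.00113, or 0.0124 adjusted over the 22 lists. After removal of the length and GC trend 17 of 23 were lower, and without the 4 libraries with over 400 genes at 0 13 were (adjusted p = 4.94e-08 for the list).

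Glycolysis genes were lower as a list (median -0.68, camera adjusted p = 0.0320; adjusted p = 0.594 with an estimated correlation), with 7 of 17 lower and 0 higher, and the same numbers adjusted over the list alone. The pyruvate kinase Pkm (-1.34), the glucose transporter Slc2a1 (-1.43), the phosphoglycerate mutase Pgam1 (adjusted p = 0.00312) and the enolase Eno1 (-0.68) fell. This call ended without Control 7 (adjusted p = 0.0614), Padi6-mutant 2 (adjusted p = 0.0550) or Padi6-mutant 6 (adjusted p = 0.120), without the 4 libraries with over 400 genes at 0 (adjusted p = 0.0861), over genes above the median level (adjusted p = 0.0795), with the number of detected genes as a covariate (adjusted p = 0.308), and after removal of the length and GC trend (adjusted p = 0.0671), when Eno1 stood at -0.32 (adjusted p = 0.125). Pkm stood at -0.85 with the trend fitted on genes with a principal transcript alone. Among genes with a mean above the median, the largest falls outside these groups included Tat, the tyrosine aminotransferase (-3.10, SE 0.58), the lipase relative Pnliprp2 (-2.12, SE 0.50), and Tex19.2, a gene of germ and pluripotent cells (-2.05, SE 0.71). Tex19.2 lost its call without Control 1, 2, 3, 6 or 7 or Padi6-mutant 2 or 7 (highest adjusted p = 0.0670) and after removal of the trend (-1.73, adjusted p = 0.0813). The calls of Slc2a1 (-0.64, adjusted p = 0.214), Pgam1 (-0.83, adjusted p = 0.0645), Eno1 (-0.36, adjusted p = 0.377), Pnliprp2 (-0.82, adjusted p = 0.210) and Tex19.2 (-2.25, adjusted p = 0.0991) ended with the number of detected genes as a covariate. The calls of Slc2a1 (-1.02, adjusted p = 0.0665), Eno1 (-0.54, adjusted p = 0.138) and Pnliprp2 (-0.85, adjusted p = 0.101) ended without the 4 libraries with over 400 genes at 0. The call of Tex19.2 (-2.05, adjusted p = 0.0559) ended without a variance trend.

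**Figure D3:**
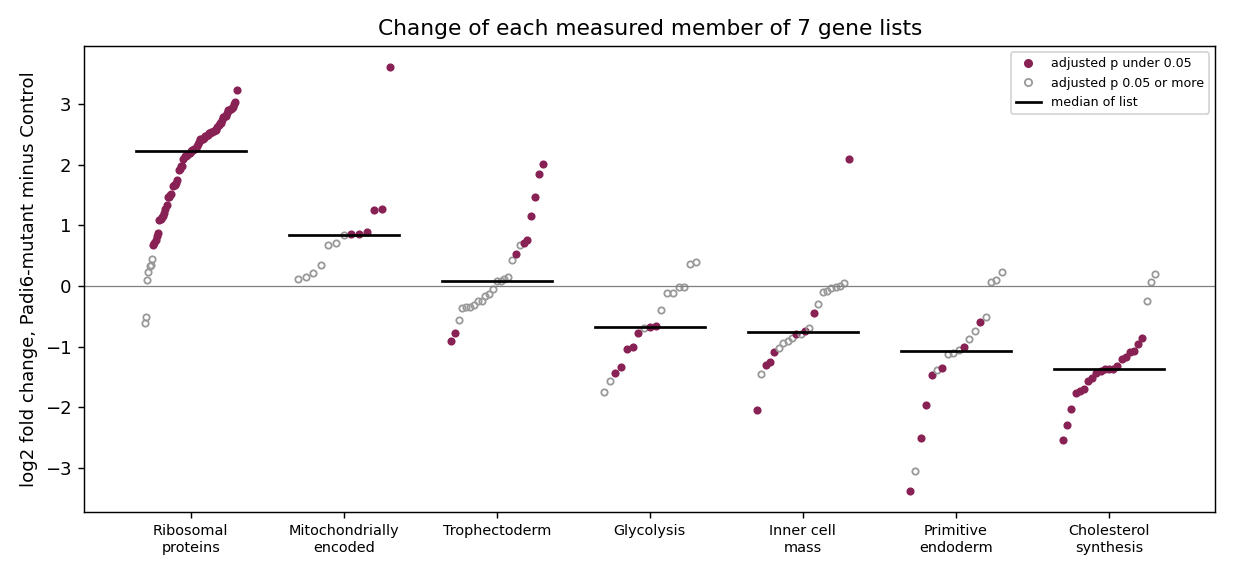
Log2 fold change (Padi6-mutant minus Control) of each measured member of 7 gene lists, filled where the adjusted p was under 0.05, with a line at the list median. The medians run from 2.22 for ribosomal proteins to -1.37 for cholesterol synthesis.

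Neither list of imprinted genes was called by camera. Of 22 measured genes expressed from the paternal allele, 4 fell and 1 rose, or 3 and 1 adjusted over the list alone (list adjusted p = 0.615). Sfmbt2, a Polycomb protein of the trophoblast, fell by 0.94, Zdbf2 by 0.79 and Jade1 by 0.68, with Gab1 (-0.67) named after its value was seen, and Mcts2, a retrogene inside H13, rose by 2.26. Of 21 expressed from the maternal allele, 4 fell and 1 rose, and the same numbers passed adjusted over the list alone (list adjusted p = 0.186), while fry gave p = 0.00326 for a fall and the list mean per embryo was 0.29 lower (exact permutation p = 0.0420, or 0.0924 adjusted over the 22 lists). H13 (-1.08), the G protein gene Gnas (-1.21) and the Igf2 receptor Igf2r (-0.48) fell, with Trappc9 (-0.75) named after its value was seen, and Commd1 rose by 1.82. After removal of the length and GC trend Mcts2 (1.19), Commd1 (1.93) and Gnas (-1.02, or -0.69 with the longest transcript) still passed. The value of Commd1 rests on a looked-up length of 4508 nt, which was not checked. Sfmbt2 (-0.73, adjusted p = 0.0597), Zdbf2 (-0.64, adjusted p = 0.0852), Jade1 (-0.31, adjusted p = 0.309), H13 (-0.57, adjusted p = 0.0777) and Igf2r (-0.09, adjusted p = 0.633) did not pass. Zdbf2 also lost its call without Control 2, 4, 5, 8 or 10 or Padi6-mutant 9 or 10 (highest adjusted p = 0.0647). The calls of Sfmbt2 (-0.62, adjusted p = 0.252), Zdbf2 (-0.70, adjusted p = 0.187) and Gnas (-0.98, adjusted p = 0.0758) ended with the number of detected genes as a covariate. The call of Zdbf2 (-0.54, adjusted p = 0.218) ended without the 4 libraries with over 400 genes at 0. The call of Zdbf2 (-0.52) ended with library quality weights. Values of a single allele were not analysed here, nor were H19, Igf2 and Xist.

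The H3K9 methylation machinery went both ways, with 3 of 22 higher and 4 lower, and the same numbers adjusted over the list alone (list adjusted p = 0.167). The heterochromatin protein Morc2a (-0.93) and the histone chaperones Chaf1a (-1.55) and Daxx (-1.22) fell, with Atf7ip (-0.49) named after its value was seen. Mphosph8, the reader subunit of the HUSH complex, rose by 1.03, as did Cbx3 (0.76) and Cbx1 (0.37), named after their values were seen. The list mean per embryo was 0.28 lower in Padi6-mutant (11.0 ± 0.15, SD, n = 9) than in Control (11.3 ± 0.17, SD, n = 10; exact permutation p = 0.00186, or 0.0137 adjusted over the 22 lists). Its median relative to all genes turned from -0.32 to 0.05 when the trend of the longest transcript was removed. Of 18 germline genes silenced by DNA methylation, 3 rose and 2 fell, and the same numbers passed adjusted over the list alone (list adjusted p = 0.715). The rises were Wfdc15a (2.25), the synaptonemal complex protein Sycp3 (1.83) and Hormad1 (1.12), and the falls Tex19.1 (-1.08) and D1Pas1 (-1.76), the last named after its value was seen. With the trend fitted on genes with a principal transcript alone Chaf1a stood at -1.02 and Daxx at -0.81. Sycp3 stood at 0.99 after removal over all genes with a length. Without the length and GC trend, Wfdc15a (0.53, adjusted p = 0.248; -0.10 with the trend fitted on genes with a principal transcript alone) and Hormad1 (0.69, adjusted p = 0.0832) did not pass. The calls of Chaf1a (-0.88, adjusted p = 0.0531), Daxx (-0.83, adjusted p = 0.199) and Hormad1 (0.95, adjusted p = 0.168) ended with the number of detected genes as a covariate. The calls of Daxx (-1.13, adjusted p = 0.0780) and Hormad1 (1.12, adjusted p = 0.0823) ended without the 4 libraries with over 400 genes at 0.

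Of 17 measured targets of p53, 3 rose and 2 fell, and the same numbers passed adjusted over the list alone (list adjusted p = 0.758). The antiproliferative gene Btg2 (1.90) and the cell cycle inhibitor Cdkn1a (1.39) rose, with Pmaip1 (1.10) named after its value was seen, and Sesn1 (-0.73) and Ei24 (-0.65) fell. The list median was -0.08 and its mean 0.19. Cdkn1a did not pass without the length and GC trend (0.60, adjusted p = 0.106). Of 15 genes of the integrated stress response 1 rose and 1 fell (list adjusted p = 0.899; median -0.17, mean 0.02), namely the stress factor Ddit3 (2.19) and the mitochondrial serine hydroxymethyltransferase Shmt2 (-1.27). Ddit3 was 1.11 with the trend removed and -2.20 (adjusted p = 4.70e-04) with the trend fitted on genes with a principal transcript alone. Both rest on a looked-up length of 105 nt at the low end of the trend, so no direction is read from them. Bst2 was 0.88 with the trend removed. Of 5 interferon response genes only Bst2 (1.85) rose (list adjusted p = 0.761; median -0.16, mean 0.12). Of 25 cell cycle genes, 2 rose and 4 fell (list adjusted p = 0.167), and at the preset correlation the list was called lower under quantile normalization (0.30 below all genes, adjusted p = 0.0289). At an estimated correlation it was not called in the values as deposited (adjusted p = 0.594). The mitotic ubiquitin-conjugating enzyme Ube2c (0.96; 0.14 with an adjusted p of 0.653 after trend removal) and the cyclin Ccne2 (0.90) rose, and the replication licensing factors Cdc6 (-0.67) and Mcm6 (-0.69) fell, as did Mcm4 (-0.56) and Mcm3 (-0.65), named after their values were seen. The counts of these 3 lists were the same adjusted over the list alone. The calls of Sesn1 (-0.74, adjusted p = 0.0654), Ei24 (-0.51, adjusted p = 0.187), Shmt2 (-0.69, adjusted p = 0.319), Ccne2 (0.68, adjusted p = 0.173), Cdc6 (-0.45, adjusted p = 0.226) and Mcm6 (-0.50, adjusted p = 0.202) ended with the number of detected genes as a covariate. The calls of Ei24 (-0.51, adjusted p = 0.107), Shmt2 (-0.97, adjusted p = 0.104), Ccne2 (0.69, adjusted p = 0.137), Cdc6 (-0.56, adjusted p = 0.104) and Mcm6 (-0.60, adjusted p = 0.110) ended without the 4 libraries with over 400 genes at 0. The calls of Sesn1 (-0.53, adjusted p = 0.0513), Cdc6 (-0.43, adjusted p = 0.109) and Mcm6 (-0.55, adjusted p = 0.0639) ended with the trend of the longest transcript removed. The calls of Shmt2 (-0.82, adjusted p = 0.0567), Bst2 (0.65, adjusted p = 0.0720) and Mcm6 (-0.51, adjusted p = 0.0502) ended with the trend fitted on genes with a principal transcript alone.

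Of 6 measured members of the subcortical maternal complex, Ooep rose by 1.93 (adjusted p = 2.35e-04) and 0 fell, or 1 and 2 adjusted over the list alone (list adjusted p = 0.899). The direction of the list turned without Padi6-mutant 7 (0.14), over genes above the median level (0.83) and after removal of the length and GC trend (0.05). Of 7 genes of the 2-cell stage 0 changed, also adjusted over the list alone (list adjusted p = 0.860), with Pramel6 at 0.30 (0.35, adjusted p = 0.0489, with library quality weights) and Pramel7 at 0.15. The only oocyte transcript measured, Cpeb1, did not pass (-1.18, adjusted p = 0.411). It was at 0 in Padi6-mutant 6 and 10, and lay at -0.58 without either of them. Of the 2 measured genes of the X inactivation centre, Rlim, the ubiquitin ligase that activates Xist, fell by 0.69 (adjusted p = 0.00121), or by 1.06 under quantile normalization, and 1 passed adjusted over the list alone (list adjusted p = 0.521). The cumulus and granulosa genes Serpine2 (0.09) and Star (-0.36) did not pass (list adjusted p = 0.941, 0 adjusted over the list alone). Y-linked genes, which follow the sex of each embryo, did not differ beyond their spread (Eif2s3y -0.75, SE 1.74; Ddx3y -0.35, SE 1.76; list adjusted p = 0.860, 0 adjusted over the list alone). For the 6 called lists fry gave p of 4.45e-06 to 0.0284. It also gave p under 0.05 for 5 lists that camera did not call, all lower, namely DNA methylation (0.00267), maternally expressed imprinted genes (0.00326), H3K9 methylation (0.00388), the X inactivation centre (0.0135) and the cell cycle (0.0247), so fry does not set the called lists apart.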

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

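The tests with thinned libraries, with the length and GC trend removed, on other short transcripts, on random lists of like length and level, on respiratory-chain genes by length, on correlated scores, on list means per embryo (by permutation or with the detected-gene covariate) and without 4 libraries were chosen only after the result was seen. Of 196 groups of values (a named gene or a measure per library, within the Padi6-mutant or the Control libraries), 19 held a library far from the others, where chance sets apart about 1 in 20 groups, or 9.8. Padi6-mutant 10 accounted for 8 of the 19 and Padi6-mutant 6 for 6.

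Padi6-mutant 10 stood below the other Padi6-mutant libraries in the pluripotency factor Sox2, which was at 0 with the next lowest library at 8.15. It was also lowest in the primitive endoderm receptor Pdgfra (2.32, next 7.79), in Pecam1 (3.70, next 7.81), in the imprint-binding zinc-finger gene Zfp57 (6.74, next 10.1), in the collagen gene Col4a1 (7.48, next 9.31) and in Sfmbt2 (9.57, next 11.0). It stood above the others in Serpine2 (13.03, next 12.18) and Pramel7 (14.71, next 14.06). Padi6-mutant 6 stood below the other Padi6-mutant libraries in the trophectoderm markers Plac1 (6.17, next 9.64), Id2 (12.5, next 14.3) and Tspan8 (13.2, next 14.7). It was also lowest in Uhrf1 (11.1, next 12.1), Chaf1a (7.77, next 9.19) and Tfcp2l1 (15.0, next 15.3). Padi6-mutant 8 was lowest in Tat (4.58, next 8.49) and Star (3.70, next 6.81). Among Control libraries, Control 6 was lowest in Cubn (8.24, next 10.6), Control 5 was lowest in Igf2r (11.8, next 12.5), and Control 9 was highest in Tspan8 (15.1, next 14.1).

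Of 100 splits of the 19 libraries into groups of 9 and 10, only the real split, 1 of 100, gave as many changed genes (3765, highest other 412), so chance is unlikely for that count. Random splits break up the length trend, and any shared litters, along with the genotype, so they do not tell these apart. For the number of called lists, 30 of 100 splits gave 6 or more (highest other 9), so chance cannot be excluded for that number as such.

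Ribosomal protein genes rose together with other short transcripts: outside the ribosomal and respiratory-chain groups, transcripts under 1000 nt lay 1.04 above the median of all genes (746 of 1719 higher, 33 lower), which argues against a rise of those groups alone. The ribosomal protein score used here is the list mean per embryo relative to all genes. With the number of detected genes as a covariate its difference was 1.78 (95% interval 1.03 to 2.53). Thinning to 1 depth, which ended 200 of the 3765 calls of genes and added 114, left the list median 2.32 above all genes (exact permutation p = 2.17e-05 for the score). The covariate value argues against fewer detected genes. The thinned values argue against counting error alone, and do not cover molecules that were never captured. Removal of each library's length and GC trend took the difference in the ribosomal protein score from 1.94 to 0.96 (exact permutation p = 2.17e-05, the smallest that the splits can give). It was 0.56 (exact permutation p = 8.66e-05) with the trend fitted on genes with a principal transcript alone. The list median also lay 0.90 above the mean of 10000 random lists of protein-coding genes of like length and level (highest 1.91, against 2.22). A rise was thus left after the trends as fitted, but its size depended on the lengths used. The random lists were not matched on GC content and took genes as independent. Control 5 (14.10) and Control 9 (14.35) had ribosomal protein means near those of Padi6-mutant 9 (14.32) and 10 (14.24). Length or GC content, alone or with abundance, may account for part of the rise, and whether it accounts for all cannot be told. For the respiratory chain, a rise of all its genes cannot be told apart from a rise of its short transcripts. Its 13 genes over 1500 nt lay 0.38 above all genes (6 higher, 0 lower), or 0.99 for 17 genes by the longest transcript. The median of the 13 was 0.28, against -0.25 for all genes over 1500 nt. Among the 6 higher were the assembly factors Ndufaf4 (0.89) and Ndufaf7 (0.59), which are not subunits of the chain. The 46 genes of the group under 1000 nt had a median of 2.53. A length was found for 74 of the 95 genes, and those without one ran from -0.39 (Ndufb11b) to 3.39 (Atp5mk). The length trend follows the groups, with Control 5 and 9 as exceptions, and the labels give no batch or RNA quality, so a difference in handling stays open, as does the genotype, which was not tested apart from it.

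Inner cell mass and primitive endoderm markers were lower, and both lists stayed called (2 of 2) at the preset correlation with libraries thinned to 1 depth. At the estimated correlation neither was called before (adjusted p = 0.594) or after (adjusted p = 0.534). Their means per embryo relative to all genes still differed (exact permutation p = 0.00372 and 0.00749, against 0.00463 and 0.00853 before thinning). This argues against counting error alone. Fewer detected genes cannot be told apart: with the number of detected genes as a covariate the difference went to -0.16 (95% interval -0.76 to 0.45, from -0.58) for the inner cell mass list and to -0.45 (-1.28 to 0.38, from -1.21) for the primitive endoderm list, intervals that hold both 0 and the difference without it. After removal of the length and GC trend the inner cell mass list lay at -0.51 relative to all genes (adjusted p = 0.0458, but 0.885 with an estimated correlation). The primitive endoderm list then lay at -0.71 (adjusted p = 0.141, from -0.98 with 0.00482). Their means per embryo relative to all genes had exact permutation p of 0.0732 and 0.0472, so an effect of length or GC content cannot be told apart for either. Fewer inner cells in some embryos is a candidate explanation that stays open: across the 9 Padi6-mutant libraries the scores of both lists rose and fell together (Pearson's r = 0.781, exact permutation p = 0.00110, 0.00220 adjusted over the 2 groups; Spearman's rho = 0.800, exact permutation p = 0.0138), but without Padi6-mutant 10 and 9 r was 0.603 (exact permutation p = 0.150), while in the 10 Control libraries r was 0.514 (permutation p = 0.129, 0.129 adjusted), rho 0.236 (permutation p = 0.516) and r without Control 9 and 1 0.324 (permutation p = 0.425). The lowest inner cell mass scores of Padi6-mutant libraries were those of 6 (11.3), 8 (11.3), 9 (10.9) and 10 (8.92). These are the 4 libraries with over 400 genes at 0, so the correlation cannot tell fewer inner cells from fewer detected genes. Padi6-mutant 2, 3, 4 and 5 lay at 11.8, 11.6, 11.5 and 11.7, and 7 at 11.6. Lower scores thus came mostly with higher numbers in the library names. What the numbers stand for is not stated, so an order of collection or handling cannot be told apart either. The inner cell mass call rested on Padi6-mutant 10, without which the list lay at -0.28 (adjusted p = 0.0996). Both calls ended without the 4 libraries with over 400 genes at 0 (-0.08, adjusted p = 0.329, and -0.59, adjusted p = 0.122), and the labels give neither cell counts nor litters.

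Cholesterol synthesis genes were lower in Padi6-mutant embryos, by 1.30 in the mean of the list relative to all genes (-1.30). With the number of detected genes as a covariate the difference was -1.24 (95% interval -2.10 to -0.37), and after removal of the length and GC trend the list lay at -1.15 and its mean still differed (exact permutation p = 0.00325), which argues against fewer detected genes and against length and GC content as the whole cause. Thinning to 1 depth left the list at -1.29 (exact permutation p = 0.00117 for its mean), which argues against counting error alone. Control 5 (10.92), 8 (10.96) and 10 (11.15) had list means within the range of Padi6-mutant libraries (9.73 to 11.26). These Control libraries, and Control 4 (12.26) and 9 (11.88), had negative Spearman's rho of GC content with the deviation from gene means (-0.27 to -0.15). In the remaining Control libraries it was 0.26 to 0.55, with list means of 11.96 to 12.98. What sets these Control libraries apart was not tested. A difference in litter or culture day stays open, since the labels name neither and both could follow the genotype. A lower transcription of the pathway in Padi6-mutant embryos is a hypothesis. Libraries from several litters per group, with dam and culture day known, would test it.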

How the results depend on the processing

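The length, longest-transcript, principal-transcript, thinning and 4-library alternatives were chosen only after the result was seen. The count of changed genes was 3765 in the values as deposited, 3963 under quantile normalization (3616 shared), 3586 without a variance trend, 3648 with a pseudocount of 0.1 and 3679 after thinning to the shallowest depth (3565 shared). It fell to 1807 (1710 shared; 1308 higher, 499 lower) with the number of detected genes as a covariate and to 2258 (705 lower) with a log2 fold change over 1 required. Under a replicate block, which also leaves out Control 1 as it has no partner, it was 2528 (2485 shared; 1000 lower), against 3035 without Control 1 alone. It was 5349 with library quality weights (3698 shared; 2689 lower), 2574 over genes above the median level (2353 shared; 1242 higher) and 2622 without the 4 libraries (2405 shared; 941 lower), against 2068 higher and 1697 lower in the values as deposited. With the trend fitted on genes with a principal transcript alone, which leaves fewer genes to test, 2018 changed (1474 shared; 1060 higher, 958 lower), against 2780 (1928 shared) with the trend over all genes with a length. The number of lists called at the preset correlation, 6, was 2 with the detected-gene covariate, 2 without the 4 libraries, 3 with the length and GC trend removed and 3 with the longest transcript. It was 5 with the trend fitted on genes with a principal transcript alone, where the mitochondrially encoded list was called lower in place of higher (adjusted p = 0.00157). It was 7 under quantile normalization, where the cell cycle list was also called (-0.30, adjusted p = 0.0289), 4 over genes above the median level and 5 with library quality weights. Thinning covers counting error, not molecules that were never captured. The ICM minus TE marker score, -0.80, was -0.89 (exact permutation p = 0.044) with the longest transcript, and the spread between embryos, 0.15, turned over genes above the median level (-0.051) and without the 4 libraries (-0.059). Over all alternatives, left-out libraries included, the camera adjusted p at the preset correlation ran from 2.31e-45 to 5.19e-17 for ribosomal proteins. It ran from 9.01e-11 to 2.63e-07 for cholesterol synthesis and 0.000661 to 0.492 for the mitochondrially encoded list. For primitive endoderm it was 0.00115 to 0.308, for inner cell mass 0.00553 to 0.348 and for glycolysis 0.0106 to 0.308. These ranges rest on the preset correlation. With an estimated one, each of the 6 lists had a camera adjusted p of 0.594 in the values as deposited. The cause was not tested where a result moved.

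Directions turned without Control 1 for interferon response list (0.013) and cumulus and granulosa list (0.0067), with the same values under the block. They turned under quantile normalization for trophectoderm list (-0.10), Nanog (-0.14) and Pramel7 (-0.019), over genes above the median level for subcortical maternal complex list (0.83), and with library quality weights for Padi6 (0.042) and Dnmt3a (-0.017). They also turned with the Y-linked level as a covariate for Y-linked list (0.096), Nanog (-0.0077) and Ddx3y (0.37), with the number of detected genes as a covariate for interferon response list (0.38), Sox2 (0.50), Pramel7 (-0.22) and Serpine2 (-0.081), and after thinning for cumulus and granulosa list (0.0033). Without the 4 libraries they turned for p53 target list (-0.086), interferon response list (0.39), Dnmt3a (-0.047), Sox2 (0.42), Pramel7 (-0.10) and Serpine2 (-0.064). Removal of the length and GC trend turned DNA methylation list (0.028), subcortical maternal complex list (0.047), integrated stress response list (0.25), interferon response list (0.59), mitochondrially encoded list (-0.18), cumulus and granulosa list (0.019), Padi6 (0.22), Dnmt3b (0.0076), Dppa3 (-0.12), Nanog (-0.0092), Cdx2 (0.038) and mt-Nd6 (-0.93). With the longest transcript it turned DNA methylation list (0.0027), H3K9 methylation list (0.049), subcortical maternal complex list (0.0065), integrated stress response list (0.25), interferon response list (0.54), mitochondrially encoded list (-0.29), Padi6 (0.18), Dnmt3b (0.0035), Dppa3 (-0.27), Nanog (-0.061), Cdx2 (0.015), Pramel7 (-0.065), mt-Nd6 (-0.90) and mt-Nd1 (-0.020). With the trend fitted on genes with a principal transcript alone it turned DNA methylation list (0.027), subcortical maternal complex list (0.080), methylation-silenced germline list (-0.068), integrated stress response list (0.054), interferon response list (0.48), mitochondrially encoded list (-0.27), cumulus and granulosa list (0.022), Padi6 (0.27), Dnmt3b (0.045), Dppa3 (-0.36), Cdx2 (0.095), Dppa1 (-0.21), Pramel7 (-0.019), Wfdc15a (-0.10), Ddit3 (-2.20), mt-Nd6 (-1.70), mt-Nd1 (-0.11) and Rps28 (-0.18).

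With each library left out in turn, 3035 to 4288 genes changed (1811 to 2262 higher, 1224 to 2026 lower), 5 to 6 lists were called, the ICM minus TE marker score ran from -1.04 to -0.44 and the spread between embryos from 0.10 to 0.20. Directions turned within these ranges: interferon response list -0.23 to 0.10, cumulus and granulosa list -0.19 to 0.18, p53 target list -0.12 to 0.13, Dnmt3a -0.032 to 0.13, Ddx3y -1.02 to 0.56, Padi6 -0.39 to 0.52, integrated stress response list -0.21 to 0.020, Nanog -0.049 to 0.11, Y-linked list -1.21 to 0.12, Eif2s3y -1.38 to 0.084, trophectoderm list -0.068 to 0.30, subcortical maternal complex list -0.41 to 0.14, Star -0.60 to 0.072, Sox2 -1.17 to 0.098, Serpine2 -0.052 to 0.19. Named genes that kept their direction but moved over 1.5-fold were Zfp57 -0.85 to -0.21, Cpeb1 -1.57 to -0.58, Pdgfra -2.75 to -1.61, Dnmt3b -0.47 to -0.24 and Pramel7 0.024 to 0.20.

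The numbers in the library names did not pair the libraries: of 9 numbers shared by both groups, correlations of the members ran from -0.07 to 0.15, with 1 over 0.1, and 1 Padi6-mutant library correlated best with its own number. Under the block the calls of Dnmt1 (-0.64, 0.0514), Uhrf1 (-0.74, 0.0834), Dppa3 (0.97, 0.0926), Gata6 (-0.47, 0.0813), Sfmbt2 (-0.86, 0.0740), Igf2r (-0.43, 0.0936), Mbd1 (-0.59, 0.0563), Sesn1 (-0.69, 0.0767), Eno1 (-0.70, 0.0681), mt-Nd6 (0.81, 0.0542), mt-Nd1 (1.16, 0.0730) and Mcm6 (-0.62, 0.0528) ended (adjusted p in brackets after the value). Of these, Uhrf1 and Dppa3 had lost theirs without Control 1 alone. A filter on detection removed no gene, so the unfiltered alternative has no value of its own. The edgeR and DESeq2 fits on recovered counts were not run, since the counts could not be worked out in 6 libraries. Genes near 0 carry little information at the lowest depth.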

Other observations

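The lists in this part and the test of X-linked genes were chosen only after the values were seen. Genes of fatty acid synthesis fell beside those of cholesterol synthesis, with 11 of 12 measured lower and 0 higher in Padi6-mutant embryos (median log2 fold change -1.56), and 10 of 12 lower after removal of the length and GC trend. The desaturase Fads1 fell by 3.99 (SE 0.93), the citrate lyase Acly by 1.66 (SE 0.25), the acetyl-CoA carboxylase Acaca by 1.55 (SE 0.16), the malic enzyme Me1 by 1.36 (SE 0.19) and the desaturase Scd1 by 1.33 (SE 0.32), each below the Control median in 9 of 9 Padi6-mutant embryos. Srebf1, the factor that drives this pathway, fell by 0.85 (adjusted p = 0.0267) and stood at -0.31 without the trend (adjusted p = 0.312). Elovl5 was the single member that did not pass (0.28, adjusted p = 0.206).

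Of 16 genes of the methionine and folate cycles, which make the methyl donor of the cell, 6 fell and 0 rose. They included Ahcy, which clears S-adenosylhomocysteine (-1.96, SE 0.28), the betaine methyltransferase Bhmt (-1.89, SE 0.63), Cth (-0.75), Mthfd1 (-0.58) and the S-adenosylmethionine synthetase Mat2a (-0.56). With the length and GC trend removed 4 of 16 were lower, among them Ahcy, Cth and Mat2a. Of 31 proteasome genes 12 rose and 2 fell. The rises were 11 of the core particle, such as Psma7 (1.89) and Psmb6 (1.42), and Psmd8 (0.61) of the regulatory particle, where Psmd2 (-0.87) and Psmd3 (-1.13) fell. After trend removal 6 were higher and 6 lower. Of 20 tRNA synthetases 0 rose and 3 fell, namely Farsa (-0.80), Mars1 (-0.60) and Rars1 (-0.36), and the length check is void for them, since a length was found for 2 of 20.

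X-linked genes were frequent among the strongest falls. Of 212 genes that fell by over 2 on the log2 scale, 18 were X-linked (8.49%, against 3.07% of all tested genes with a chromosome), where 10000 random lists matched on the Control level held 6.82 on average and 18 at most (random-list p = 3e-04). That p treats genes as independent and does not measure variation between embryos. They included Arxes2 (-5.02), Bhlhb9 (-4.96), Magea5 (-4.94), Gprasp2 (-4.27) and Maged2 (-3.84), and 11 of the 18 were below the Control median in all 9 Padi6-mutant libraries. Over all 410 X-linked genes, 53 rose and 53 fell, and the mean X-linked level relative to other genes did not differ beyond its spread (difference -0.11, exact permutation p = 0.401). A hypothesis is that some X-linked genes may be more prone than others to fall with the genotype. The count of 18 was found and tested on the same libraries, and depth was not tested as its source. Y-linked list means ran from 1.40 to 11.5 in Padi6-mutant libraries and did not differ between the groups (exact permutation p = 0.636). The 11 genes below the Control median in all 9 thus fell at low and high Y-linked levels, which argues against sex as the source for them. Sex was not tested for the other X-linked falls. Libraries of further Padi6-mutant embryos would test the hypothesis.

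The counts worked out from the values, 12.1 to 46.2 M in the listed genes per library, exceed the mean depth of 4.2 M reads that the labels give, and the difference was not resolved here.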
